A study of Homo sapiens with 12 samples.

How the data were processed

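Chromatin isolation by RNA purification followed by sequencing (ChIRP-seq) was performed in Jurkat cells, an established human T-cell leukaemia line, which per the labels' protocols had been made to express the long non-coding RNA SLEAR stably. In this assay, crosslinked chromatin is captured with biotinylated oligonucleotides that pair with an RNA, and the DNA that comes with it is sequenced. Probes against the RNA are divided into an odd and an even set that have no oligonucleotide in common, and probes against the bacterial lacZ RNA, which human cells lack, serve as the negative control. The labels name 12 samples in 4 groups of 3: input, lacZ, odd and even. Peak lists of 9 samples were used, 3 each of lacZ, odd and even; the 3 input samples and any merged files were not analysed here.

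Reads were checked with FastQC and aligned with Bowtie2 to the human genome build hg19, per the submitters' processing notes, which give no versions in the sources used here. The peak caller, its settings and the control library it used are not given in the sources used here. The columns are in the layout that MACS2 writes, per the file headers. Peaks were called separately in each sample, since each deposited list carries its own sample's peak names. The deposited lists give the position, length and summit of each peak in bases, counted from 1 with both ends included. The pileup is a signal, the coverage by fragments at the summit, and was deposited as whole numbers that were not scaled to depth. The significance is deposited as −log10 of the p-value and −log10 of the q-value. The fold enrichment is a ratio of the summit pileup to a background, per the file headers; whether that background came from the same library or from an input is not given in the sources used here. This fold is the authors' value for a peak in its own list, and it was used to describe, rank or filter peaks within that list. For named regions its mean and SD over the lists of a set are given as a description only. That SD also includes differences in scale between lists. Folds given side by side for different lists are not compared, since their depth is unknown.

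The total number of reads behind each list is unknown, so no interval for sampling of reads was computed. The lowest background that the pileup and fold imply in each list, divided by the shortest peak length, was taken as a rough guide to depth, which holds only if the background follows the depth of the same library. Replicates were labelled 1, 2 and 3 in each group. Nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

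Chromosomes 1 to 22 and X were used for the main results. The number of peaks in the 6 probe lists was compared with that in the 3 lacZ lists on the log2 scale by an exact permutation test, two-sided, over all 84 choices of 3 libraries out of 9, which cannot give a p below 0.0119. Overlap of 2 lists was measured by the Jaccard index, the bases in both lists over the bases in either, and the 15 pairs of probe lists were compared with the 18 pairs of a probe and a lacZ list over the same 84 choices. Peaks of all 9 lists that overlapped by at least 1 base were merged into regions. A candidate region had a peak in at least 5 of the 6 probe lists and in no lacZ list. A lacZ-only region had a peak in all 3 lacZ lists and in at most 1 probe list. Both counts were set against the counts that the same rule gave for the other choices of 3 control libraries. Odd-only and even-only regions had a peak in all 3 lists of one probe set and in none of the other, and were compared over the 10 splits of 6 lists into 3 and 3, whose share cannot go below 0.1.

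These rules, the alternatives except the Jaccard index over rigid shifts and the requirement of close summits, and the rule for the regions named in the text were fixed before the data were examined. The rule took the 20 candidate regions with the highest mean percentile of fold within each list, and the 5 lacZ-only regions and 5 regions present in all 9 lists that ranked highest in the same way. As a measure of chance chosen after the lists had been looked at, all lists of one set were moved rigidly by 50 to 500 kb in either direction in steps of 50 kb, which gives 20 shifts that keep the spacing of peaks within the set. The share of shifts with a count at least as large, the real position included, is given as a one-sided permutation p that cannot go below 0.0476. Summit distances between sets used the median summit of each set's lists in a region. The alternatives were stricter lists, lists of equal length, other ways to merge or to call presence, other overlap measures, all sequences in the lists, a replicate block, and leaving out replicates.

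The gene table at hand follows assembly GRCh38, another build than the lists. Its coordinates were not used, so the regions are named by position, and the planned comparison of promoter shares and the planned tests of the gene lists were not run. The table gave only the name, type, chromosome and length of the gene of SLEAR. The region rule, the overlap code and the shifts were tested on simulated lists for the comparison of 6 probe with 3 lacZ lists, with 762951 peaks placed at random and 200 regions planted in all probe lists. Of these, 195 regions, or 97.5%, were recovered as candidate regions among 3090 that met the rule, most of them by chance overlap, and for unrelated sets the observed count was 0.993 times the shifted one. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.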

Results

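Peaks of ChIRP-seq with odd, even and lacZ probes were compared in Jurkat cells that stably expressed SLEAR, to find the stretches of chromatin that came down with this RNA. Each probe set was used in 3 libraries. The 3 lacZ lists held 46693, 91111 and 26540 peaks, the 3 odd lists 66520, 106284 and 117481, and the 3 even lists 94452, 90519 and 124668. The median fold enrichment of a list, a value the authors gave per peak, lay between 9.96 and 12.5 in all 9. The lowest background implied by pileup and fold, a rough guide to depth, ranged from 2.16 fragments per kb in lacZ replicate 3 to 5.92 in even replicate 2. Within each probe set it was lowest in replicate 3, at 2.16, 3.13 and 3.06 fragments per kb for lacZ, odd and even.

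The probe lists were compared with the lacZ lists to see how many peaks the control probes gave in the same cells. Odd and even probes gave more peaks than lacZ probes. The odd lists held 96762 ± 26782 peaks (SD, n = 3), the even lists 103213 ± 18684 and the lacZ lists 54781 ± 33037. On the main chromosomes the geometric mean was 2.03-fold higher in the 6 probe lists than in the 3 lacZ lists, a log2 difference of 1.02 (exact permutation test, two-sided, p = 0.0357). With a replicate block the exact permutation p was 0.0741, where 27 arrangements allow 0.037. With odd or even lists alone the difference was 0.96 or 1.08 (exact permutation p = 0.2 each, where 3 against 3 cannot go below 0.1). The sets overlapped, since lacZ replicate 2 held more peaks than odd replicate 1 and even replicate 2. The rough guide to depth was also lower in lacZ lists, at 3.26 ± 0.963 fragments per kb, against 4.26 ± 1.05 in odd and 4.68 ± 1.47 in even lists (SD, n = 3). How much of the difference in peak number comes from depth was not tested. Peaks covered 41.5 ± 9.94 Mb in odd, 46.2 ± 6.98 Mb in even and 24.6 ± 13.6 Mb in lacZ lists (SD, n = 3). Without the libraries numbered 3, among which lacZ replicate 3 had the shortest list, the log2 difference was 0.43 (exact permutation p = 0.4), and without those numbered 1 it was 1.15 (p = 0.133), in exact comparisons that cannot give a p below 0.0667.

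**Figure D1:**
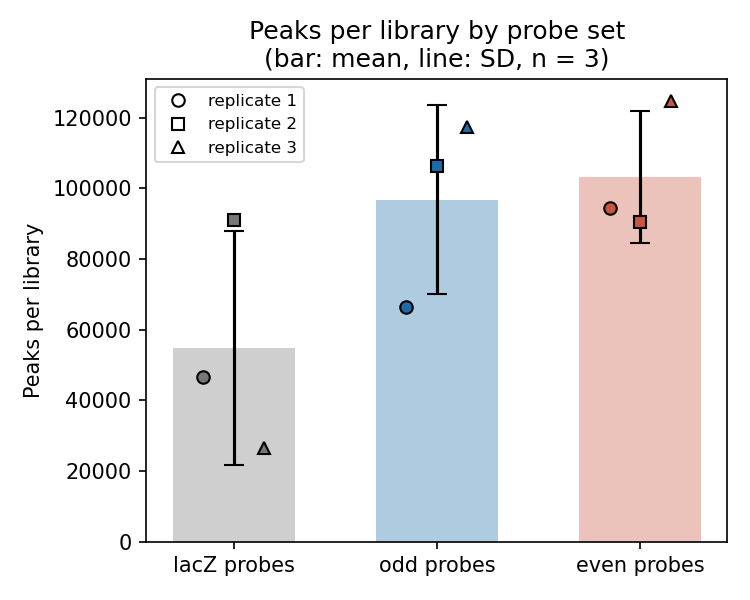
Number of peaks in each of the 9 libraries by probe set. Bars are means, lines are SD (n = 3), and points are single libraries; the lacZ mean of 54781 lies below the odd mean of 96762 and the even mean of 103213, with lacZ replicate 2 inside the range of the probe lists.

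The odd and even sets share no oligonucleotide, so overlap of their peaks was set against their overlap with lacZ peaks. Peaks recurred among the 3 lists of one probe set and were seldom shared between sets. The Jaccard index was 59.5% ± 2.23 among even lists, 55.2% ± 4.7 among odd lists and 42.1% ± 10.3 among lacZ lists (SD over 3 pairs each). Odd and even lists shared 1.33% ± 0.139 (SD over 9 pairs). Even and lacZ lists shared 0.634% ± 0.224, and odd and lacZ lists 0.598% ± 0.205 (SD over 9 pairs each).

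Every odd-even pair, from 1.14% to 1.46%, lay above every pair of a probe and a lacZ list, which reached 0.965%. The 15 pairs of probe lists averaged 23.7% and the 18 pairs with lacZ 0.616%, a difference of 23.1 percentage points (exact permutation test, two-sided, p = 0.0119, the smallest that 84 choices allow). That average is carried by the pairs within the odd and within the even set, so this p does not test whether odd and even lists share sites. With the index divided by that after rigid shifts, the same comparison gave an exact permutation p = 0.0357. Relative to the index after rigid shifts, which allows for list length, odd-even pairs stood at 1.65 ± 0.0921, even-lacZ pairs at 1.14 ± 0.0243 and odd-lacZ pairs at 1.10 ± 0.0236 (SD over 9 pairs each), with no overlap between the odd-even range, from 1.53, and the highest lacZ pair, 1.18.

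**Figure D2:**
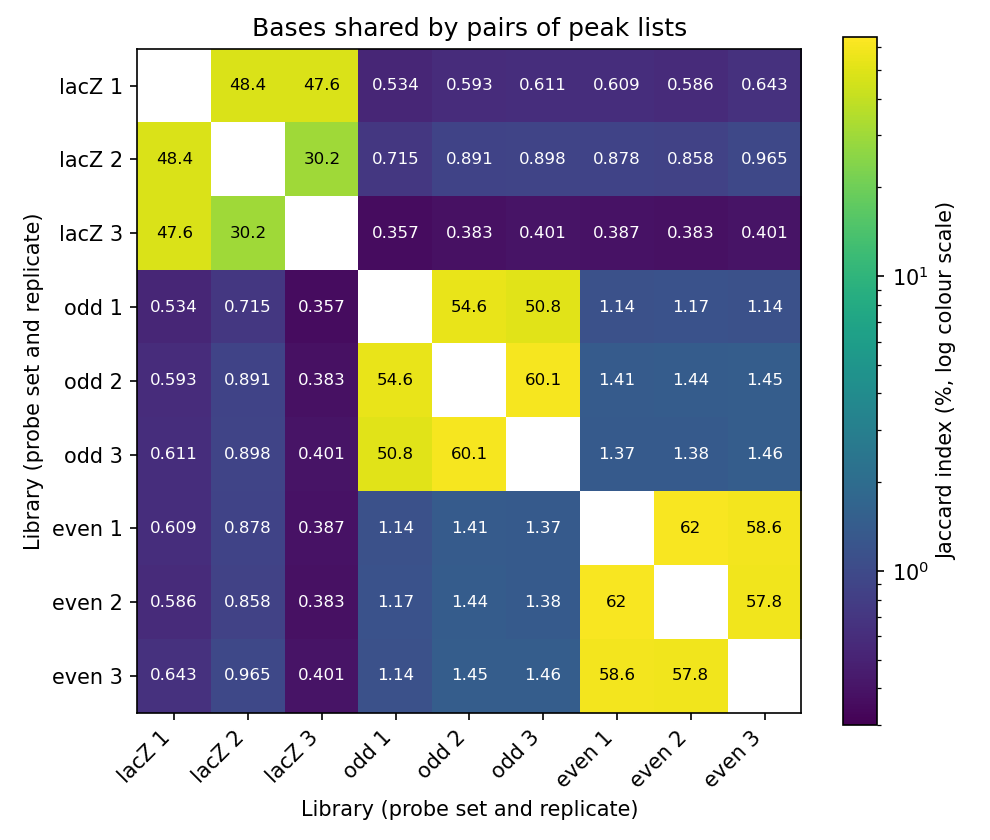
Jaccard index in percent for each pair of the 9 lists, on a log colour scale, with libraries on both axes. The 3 blocks along the diagonal hold values from 30.2% to 62.0%, odd-even pairs lie between 1.14% and 1.46%, and pairs with lacZ do not exceed 0.965%.

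Regions found with both probe sets and not with lacZ are the sites that the design takes as contacts of SLEAR. Of 357901 merged regions, 4042 (1.13%) had a peak in at least 5 of the 6 probe lists and in no lacZ list, with a median length of 873.5 bases. Of these, 2334 had a peak in all 6 probe lists. A further 244 regions met the rule for the probe lists and also had a lacZ peak. The same rule with any other 3 libraries in place of lacZ gave at most 1571 regions, with the 3 odd lists as the control, so the real control ranked 1 of 84 (share 0.0119). Odd and even lists moved apart by rigid shifts also gave more regions than that, at least 2922, so the rank alone does not separate shared sites from chance overlap.

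The highest ranked candidate region by mean percentile of fold lay on chromosome 8 from 102063875 to 102065444 (positions on hg19 here and below). Its fold enrichment was 321 ± 271 in odd and 365 ± 183 in even lists (SD, n = 3), and the summits of the sets lay 1 base apart. The second was on chromosome 3 from 113698402 to 113700448, with a fold of 179 ± 92.1 in odd and 123 ± 32.7 in even lists and summits 993 bases apart. The third, on chromosome 1 from 93611963 to 93612908, had a fold of 350 ± 155 in odd and 98 ± 36.8 in even lists, with summits 59 bases apart. On chromosome 18 the region from 14444193 to 14445698 had a fold of 280 ± 208 in odd and 95 ± 34.6 in even lists. On chromosome 13 the region from 19188278 to 19189875 had 299 ± 144 and 86.7 ± 7.36, with summits 13 bases apart.

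The 20 highest ranked candidate regions lay on 13 chromosomes, and all 20 had a peak in all 6 probe lists. Their mean percentile of fold within a list ran from 97.6 to 99.94. In 11 of the 20 the odd and even summits were within 100 bases, as on chromosome 14 from 68064938 to 68065845 (3 bases), chromosome 9 from 100578731 to 100579690 (4 bases), chromosome 5 from 97070984 to 97072236 (9 bases) and chromosome 20 from 33403573 to 33404504 (2 bases). Summits lay farther apart on chromosome 9 from 107960781 to 107962416 (745 bases) and on chromosome 3 from 72035719 to 72037372 (737 bases). On chromosome 12 the region from 120349211 to 120350669 had a fold of 76 ± 30.4 in odd and 219 ± 31.9 in even lists (SD, n = 3).

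**Figure D3:**
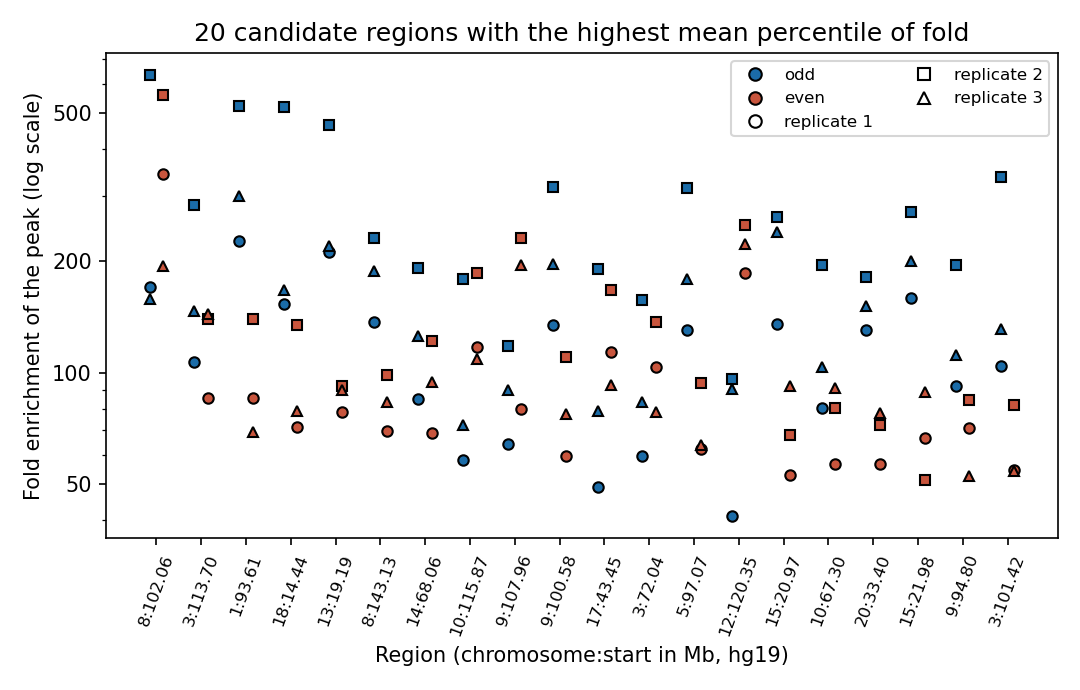
Fold enrichment of the strongest peak in each of the 6 probe lists (log axis) for the 20 candidate regions with the highest mean percentile, ordered by rank; colours are probe sets and symbols are replicates. The set means run from 76 to 350 in odd lists and from 63.7 to 365 in even lists.

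Peaks of unrelated sets also meet by chance, and rigid shifts of the even lists gave 3014 ± 52.9 regions (SD over 20 shifts), between 2922 and 3148. The observed 4042 were 1.34 times as many (permutation p = 0.0476, one-sided, the smallest that 20 shifts allow). The rule applied to lacZ and even lists without odd peaks gave 1571 regions, 1.06 times the shifted 1487 ± 46.9 (permutation p = 0.0952). For lacZ and odd lists without even peaks it gave 1494, 1.11 times the shifted 1350 ± 41.9 (permutation p = 0.0476).

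The ratio was highest where the odd and even summits coincided. In 850 candidate regions they lay within 50 bases, 3.09 times the 275 ± 14.6 after shifts, and in 449 within 51 to 100 bases, 1.61 times the 278 ± 22.7. Beyond 100 and up to 200 bases the ratio was 1.204, beyond 200 and up to 500 bases 1.09, with 1522 regions, and beyond 500 bases 1.10, each above all 20 shifts (permutation p = 0.0476). With lacZ in place of one probe set, the ratio within 50 bases was 1.15 for either pair, and at 51 to 100 bases it was 1.07 for lacZ with even lists (permutation p = 0.333) and 1.33 for lacZ with odd lists (permutation p = 0.0476). Beyond 500 bases lacZ with odd lists stood at 1.21 (permutation p = 0.0476), above the odd-even ratio. In all, 1299 candidate regions (32.1%) had summits within 100 bases, against 18.3% after shifts, where the highest share was 19.4%. Between single lists, the share was 96.4% to 97.3% for 2 lists of the same set and 29.4% to 32.5% for an odd and an even list. The candidate count ranged from 464, when every list was held to the same length (343 with the next choice of controls), to 6820, when 4 probe lists sufficed. Without the libraries numbered 1, where 3 of 4 probe lists were required, it was 6726.

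**Figure D4:**
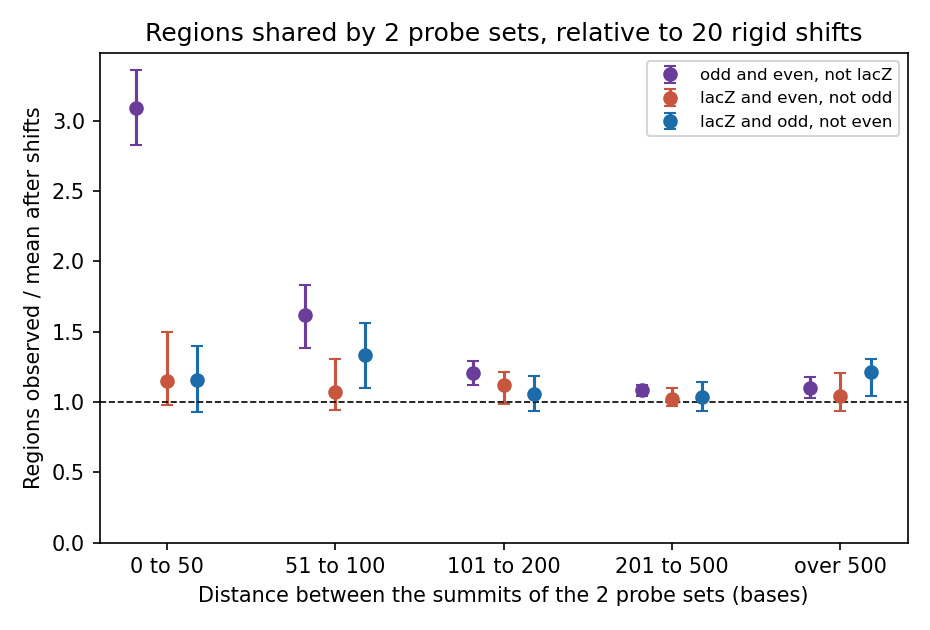
Regions shared by 2 probe sets and absent from the third, divided by their mean after 20 rigid shifts, by the distance in bases between the summits of the 2 sets. Points are ratios, and lines span the ratios to the highest and lowest shifted count; odd-even regions reach 3.09 within 50 bases, while both lacZ pairs stand at 1.15.

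Peaks with a higher fold lay more often in regions of the other probe set, and they were also longer. Of the 10% of peaks with the highest fold in odd replicate 1, 11.02% lay in a region with at least 2 even lists, against 4.85% of the 10% with the lowest fold, and their median lengths were 765 and 294 bases. In odd replicates 2 and 3 the highest 10% gave 9.01% and 8.54%, against 5.03% and 4.10% of the lowest 10%. In the even lists the highest 10% gave 7.61%, 7.62% and 6.62% with the odd set, against 4.91%, 5.16% and 3.63%. These strongest peaks lay in a region with at least 2 lacZ lists in 2.55% to 2.71% of cases, and the weakest in 1.48% to 2.11%. In lacZ replicate 3 the order was the other way for odd regions, with 4.40% of the strongest and 4.95% of the weakest peaks. How much of these differences comes from peak length was not tested.

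The region with the highest mean percentile of fold over the probe lists, whatever lacZ showed, was chosen after its values were seen. It lay on chromosome 8 from 102086950 to 102088916 and had a fold of 563 ± 396 in odd and 587 ± 203 in even lists (SD, n = 3). It was the strongest peak in each of the 3 even lists, and ranked 2, 2 and 3 in the odd lists. It did not count as a candidate region because 2 lacZ lists had a peak there, with a fold of 19.3 in replicate 2 and 4.19 in replicate 3. The next in rank was the first candidate region, on the same chromosome. Between them, a region from 102066298 to 102067245 had a peak in all 6 probe lists, with a fold of 117 ± 72.5 in odd and 7.08 ± 1.45 in even lists. The 3 lacZ lists had a peak from 102080883 to 102081783, with a fold of 56.1 ± 43.2 (SD, n = 3), where odd replicate 2 also had one, with a fold of 7.42.

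**Figure D5:**
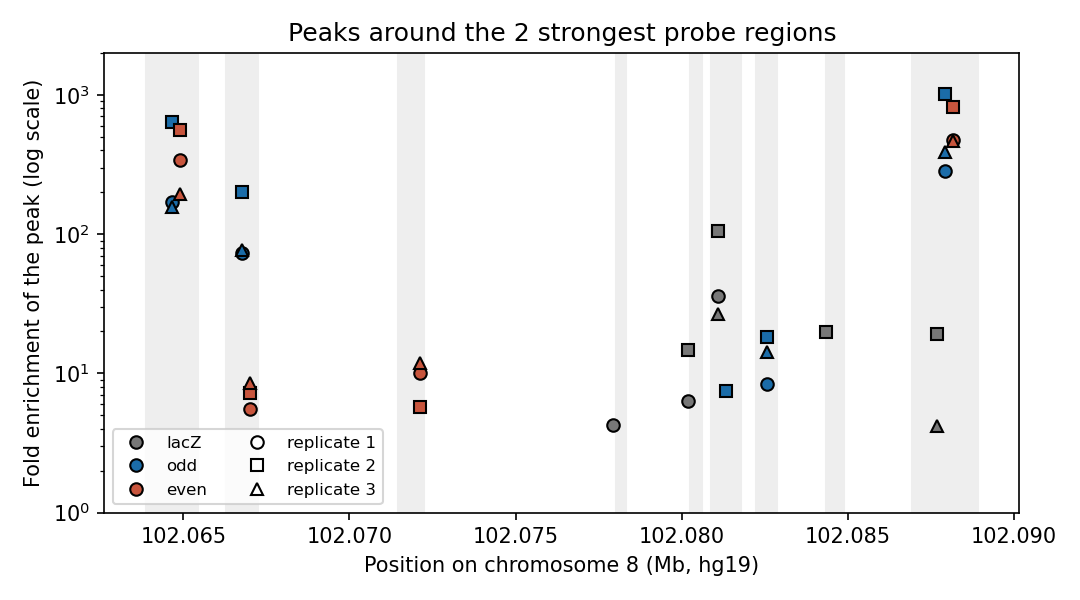
Fold enrichment (log axis) of peaks by position on chromosome 8 in Mb (hg19); grey bands are merged regions, colours are probe sets, which are offset sideways for legibility, and symbols are replicates. Both outer regions hold peaks of all 6 probe lists with a fold from 157.7 upward, and lacZ replicates 2 and 3 have a peak in the one at the higher position.

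The rule was turned round to see what the control probes found alone. With lacZ, 21935 regions had a peak in all 3 lists and in at most 1 probe list. The highest ranked was on chromosome 14 from 70870301 to 70871225, with a fold of 289 ± 229 (SD, n = 3) and no probe peak. The next were on chromosome 10 from 129069215 to 129070163 (273 ± 190), chromosome 6 from 38007222 to 38008146 (275 ± 208), chromosome 14 from 39295481 to 39296441 (277 ± 213) and chromosome 7 from 84433864 to 84434814 (258 ± 193). The count was larger than that of all but 2 of the 84 choices (share 0.0357), and the even lists in the place of lacZ gave 64262. Without lacZ replicate 3, the shortest list, it was 40307.

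Only 49 regions had a peak in all 9 lists. The highest ranked lay on chromosome 9 from 132688771 to 132690047, with a fold of 153 ± 60.9 in odd, 41.6 ± 11.4 in even and 161 ± 104 in lacZ lists (SD, n = 3). On chromosome 6 the region from 32739474 to 32740701 had 142 ± 59.6 in odd, 24.5 ± 7.77 in even and 34.8 ± 31.3 in lacZ lists. The other 3 were on chromosome 7 from 36710048 to 36711205, chromosome 20 from 31984087 to 31985438 and chromosome 10 from 78491045 to 78493279, with lacZ folds of 73.7 ± 52, 46.7 ± 28.4 and 81.4 ± 53.9.

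The odd and even sets were compared with each other, since both are aimed at the same RNA. In 54075 regions all 3 odd lists and no even list had a peak, out of 58510 with a peak in all 3 odd lists. In 64273 regions all 3 even lists and no odd list had one, out of 69242. Peaks in the top 10% by fold recurred in all 3 lists of their own set in 99.6% to 100% of cases in each of the 9 lists, lacZ included. Over all peaks of a list the share was 26.5% in lacZ replicate 2 to 90.9% in lacZ replicate 3, and in the lowest 10% by fold 0.343% to 57.0%. Any other split of the 6 lists into 3 and 3 gave at most 267 such regions, and 10 splits cannot give a share below 0.1. With every list held to the same length the counts were 20331 odd-only and 19956 even-only regions.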

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

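The checks in this part were chosen after the data had been seen, and the sequences concerned were not used for the comparisons above. They concern sequences that hg19 places outside the assembled chromosomes, and mitochondrial DNA, where all 3 lists of a probe set held at least 5 peaks and more than any lacZ list, both in number and per 10000 peaks of the list, or a peak that no lacZ list had. On chr9_gl000199_random the even lists held 40.3 ± 4.93 peaks (SD, n = 3), against at most 7 in a lacZ list and at most 1 in an odd list. On chr1_gl000192_random the even lists held 33.7 ± 2.89 peaks, the odd lists 23.7 ± 5.86 and the lacZ lists at most 22. On chr19_gl000209_random both probe sets stood above lacZ, with 12.7 ± 2.52 peaks in odd and 10.3 ± 4.16 in even lists, against at most 4. Smaller numbers came from chrUn_gl000217 with 7.33 ± 2.31, chrUn_gl000222 with 6.33 ± 0.577 and chrUn_gl000216 with 5 peaks in each of the even lists, against at most 3, 5 and 2 in a lacZ list; the odd lists were close to the even ones there, with 6.33 ± 2.08, 5.67 ± 2.08 and 4.33 ± 1.53.

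On mitochondrial DNA the 3 odd lists had a peak from 6909 to 7817 with a fold of 17.9 ± 3.29 (SD, n = 3) and a weaker one from 3892 to 4291 with 3.77 ± 1.65, and neither the even nor the lacZ lists had a peak in them. No probe list stood apart from the other 5 in its number of peaks, covered length, median or highest fold, median peak length or background by the gap to its neighbour over the range. No explanation was tested for these values.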

How the results depend on the processing

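The Jaccard index over rigid shifts and the requirement of close summits were chosen after the data had been seen; the other alternatives were planned. The log2 difference in peak number could not be changed in size by taking the stronger part of each list by fold or by the replicate block. It kept its direction under all 9 alternatives, but its side of 0.05 in only 3 of them, and 6 were weaker. It was 1.02 (exact p = 0.0741) with a replicate block, 0.96 (exact p = 0.2) with odd lists alone and 1.08 (exact p = 0.2) with even lists alone, where exact tests of 3 against 3 cannot go below 0.1, and 0.43 to 1.48 without each replicate in turn, with exact p = 0.4 without replicate 3 and 0.133 without replicate 1. The overlap difference kept its side of 0.05 in 8 of 11 alternatives. Without each replicate it was 18.6 to 19.97 points, where p cannot go below 0.0667.

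The 4042 candidate regions became 1280 in the stronger part of each list by fold, 464 in lists of equal length, 6533 with peaks merged over 500 bases, 1117 where a list had to cover at least 50% of a region, 2334 with 6 of 6 and 6820 with at least 4 of 6 probe lists, and 1299 with summits within 100 bases. Leaving out replicates gave 4043 to 6726. The real controls gave the highest count in all 18 comparisons of choices, with 343 for the next choice at equal length and 3362 against 4139 when 1 lacZ list was allowed. The lacZ-only count was 12242 in the stronger part by fold and 22147 to 41279 when replicates were left out, with the highest values, 41279 and 40307, without replicate 3 of all sets or of lacZ. The odd-only count was 30127 in the stronger part by fold and 20331 at equal length, and the even-only count 36110 and 19956. Stricter and shorter lists hold fewer peaks by construction; otherwise the cause was not tested.

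The difference in mean Jaccard index between pairs with the same and with different numbers was −17.1 points (exact permutation p = 0.667). At equal length it was −21.6 (exact permutation p = 0.0278, the smallest possible). Its sign is fixed, because no pair within a set shares a number. The p compares the difference with 36 reassignments of the numbers around their own mean, so it does not rest on that sign. With the index divided by that of shuffled peaks, the exact permutation p was 0.0556. Across sets the index was 0.858% for the same number and 0.851% for different ones, and 0.406% and 0.401% at equal length. Deviations of same-numbered lists from their set correlated between −0.0594 and 0.0992 over 9 pairs, and 7 of 18 best matches had the same number. The numbers were therefore not taken to pair the libraries. Overlap of positions can hardly show a shared batch, because peaks are seldom shared between sets. Background was lowest in replicate 3 of lacZ, odd and even, at 2.16, 3.13 and 3.06 fragments per kb. The highest fold of a list was largest in replicate 2, at 575, 1149 and 822. Peak number had no such order, since replicate 3 was shortest in lacZ but longest in odd and even. These values and the low p at equal length leave a tie between same-numbered libraries open. With the replicate block the overlap of odd with even lists exceeded that with lacZ by 0.727 points (exact p = 0.037, the smallest of 27 arrangements) and 4214 candidate regions were counted, against at most 3590 in another arrangement. For the lacZ-only regions it gave 21146, a count that 3 of 27 arrangements reached (share 0.111), and without replicates the share was 0.2 to 0.25. The promoter and gene list comparisons and their alternatives were not run. The total reads per library are unknown, so sites under the calling threshold cannot be told from missing ones.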

Other observations

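The tests of spread over chromosomes, of strong regions with close summits, of capture without the target RNA, of contacts as most peaks, of sites common to any probe set by summit distance and of the chromosome 8 regions were chosen after the result was seen. The excess of candidate regions over the mean of the shifts was also chosen afterwards as a criterion. The comparisons over choices and splits of libraries were planned, and how to read them was settled afterwards. The spread of peaks over chromosomes differed between probe and lacZ lists. Chromosome 1 held 8.60% ± 0.0861 of the peaks of a probe list (SD, n = 6) and 8.22% ± 0.102 of a lacZ list (SD, n = 3), and chromosome 11 held 4.98% ± 0.0621 and 4.70% ± 0.133. The probe lists had a lower share on chromosomes 6 (5.79% against 6.15%), 7 (5.42% against 5.59%), 12 (4.79% against 5.23%) and 13 (3.34% against 3.73%). These 6 of 23 chromosomes each had an exact permutation p = 0.0119, the smallest possible, which is 0.0456 after Benjamini-Hochberg adjustment. Lists of one probe set share many of their peaks, so they are not independent. The p therefore does not separate an effect of the target RNA from a difference among the 3 probe sets.

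Candidate regions were also spread unlike the regions of a single probe set. Chromosome 20 held 3.93% of candidate regions and 2.74% of regions found by all 3 lists of one probe set only (odds ratio 1.45, adjusted p = 0.000399, Fisher's exact test over 23 chromosomes), and chromosome 10 held 6.04% and 5.07% (odds ratio 1.203, adjusted p = 0.0408). The share was lower on chromosome 4 (3.81% against 4.94%, odds ratio 0.762, adjusted p = 0.00642) and on X (2.15% against 3.14%, odds ratio 0.679, adjusted p = 0.00251) by the same exact test. Regions are not replicates, so these p-values describe these lists. A candidate region needs peaks of both sets to meet, which happens by chance more often where peaks are dense. Shifted lists also gave 3014 ± 52.9 such regions (SD over 20 shifts), whose spread over chromosomes was not counted. These tests therefore cannot tell a difference in shared sites from chance overlap. Among the strongest regions, 25 had close summits and lay above percentile 90 of fold in both sets, against 5.35 ± 2.58 after shifts. The same class held 2 regions for lacZ with even lists, against 2.95 ± 1.73 after shifts, and 0 for lacZ with odd lists, against 2.5 ± 1.61.

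Peaks recurred within a probe set and were seldom shared between sets. List length cannot account for this: with 26460 peaks in every list, the Jaccard index within sets was still 162 times that between sets. Contacts of SLEAR as most of the peaks of both sets are argued against, since the odd-even index was 0.804% of the index within the odd and even sets. A hypothesis left open is that each set may capture its own sites without the target RNA, and the lacZ probes, whose RNA the cells lack, recurred at 87.0% of the level of the odd and even sets. Whether oligonucleotides pair with the DNA or with other RNAs at these sites was not tested.

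Regions found by both probe sets and not by lacZ are not coincidence alone, since the 4042 exceeded all 20 shifted counts, up to 3148. Whether a shared contact lies in most of them cannot be told by the test set beforehand. The share with close summits, 32.1%, lay below the bound of 48.4% for it and above the bound against it, the 19.4% that shifts reached. The bound of 48.4% came from pairs of single lists, for which the odd-even share averaged 30.9%. The excess over the mean of the shifts, a measure added afterwards, was 25.4% of the regions, which argues against a shared contact in most of them. Sites that any 2 probe sets recover stay possible by the test set beforehand: the overall ratio was 1.21 times that of the higher lacZ pair, within the bound of 1.5. The 1299 regions with summits within 100 bases, a class tested only after the result was seen, hold 72.6% of the excess. For them that quotient was 1.89, above the bound. This cannot decide against such sites there, because each count leaves out regions with a peak in the third set. The lacZ lists held fewer peaks on average, so sites of any probe set that lacZ misses count as odd-even. How far this raises the quotient was not tested. For regions with summits farther apart the quotient was 1.03, so sites that any 2 probe sets recover may account for the rest of the excess. A contact of SLEAR in part of the regions with close summits stays open as a hypothesis, as does sequence that pairs with probes of both sets.

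The 2 regions with the highest mean percentile of fold over the probe lists were both on chromosome 8. They were not the strongest in every list: the one that starts at 102063875 ranked 18, 6 and 287 in the odd lists and 5, 2 and 97 in the even lists. One hypothesis is that these 2 regions lie at the ends of the gene of SLEAR. The outer ends of the regions are 25042 bases apart, and the gene, a long non-coding RNA gene on chromosome 8 in the GRCh38 table, is 24198 bases long, a difference of 3.49%, so the regions may mark the gene itself. Both were ranked without regard to lacZ; a site that every probe set recovers is argued against, since 0 of 3 lacZ lists had a peak in the top 10% of its fold in either region, and the best of the 2 lacZ peaks in the region that starts at 102086950 lay at percentile 68.4. DNA of the introduced copy cannot be told apart from the chromosomal gene: between the regions all 6 probe lists had a peak, with a pileup that was 25.4% to 29.0% of that in the weaker region of the same list in odd lists and 0.89% to 1.80% in even lists. Probes that pair directly with the DNA of the gene would give the same peaks and were not tested.

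For the candidate regions 1 of 84 choices of controls, the real one, reached 4042 and the highest other gave 1571. This does not bear on chance, because unrelated odd and even lists, moved apart by shifts, also gave at least 2922. For the lacZ-only regions 3 of 84 choices reached 21935, a share of 0.0357. The others were the odd and the even lists in the place of lacZ, with up to 64262 regions, several times the real count. The lists of these samples therefore group by set. Whether the probes or something else that the lists of a set share lies behind this was not tested. For the odd-only (54075) and even-only (64273) regions 1 of the 10 splits, the real one, gave a count as large and the highest other gave 267; 10 splits are too few for a share under 0.05.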
